A study of Mus musculus with 12 samples.

How the data were processed

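RNA of 12 mouse placentae at E19.5 was sequenced in 3 groups of 4 libraries, ICSI-F1, ICSI-F2 and control. Per the labels' protocols, tissue was homogenised, total RNA was extracted with a miRNeasy kit and DNase treatment, and stranded libraries of mRNA were made. The sample labels and the series description name different stranded Illumina kits. They also differ on the number of samples, 12 in the labels and 8 in the description, and on whether ICSI-F2 came from in vitro fertilisation or natural mating. Sequencing was single-read, 76 bp, on a NextSeq 550, per the series description.

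The deposited values are raw read counts per gene, made by the authors with HTSeq per the sheet's name and title line. The submitters' processing notes name bcl2fastq 2.20, cutadapt 3.4, HISAT2 2.2.1 and HTSeq 2.0.2 with genome build mm10. The role and parameters of each tool, the strand setting of the counting and the annotation release are not given in the sources used here. The table held 32285 genes and 12 columns, each matched to a sample by its title. Of its gene names 27 had been turned into dates by a spreadsheet and were restored by gene ID. Coordinates, 1-based on mm10, came from a GENCODE annotation in which 32158 of the IDs were found. No entry without a gene was present. Placenta from natural mating, the control, gives the background for every measure.

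Genes were kept by edgeR's filterByExpr (minimum count 10), which left 15521. Counts were scaled by TMM factors and fitted with edgeR 4.0.16 in R 4.3.3, in a single model of 3 group means over all 12 libraries with 9 residual degrees of freedom. The common dispersion was 0.0286. The quasi-likelihood F test (robust, legacy mode) gave each p, and adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. CPM are counts scaled to the effective library size, and a prior count of 2 was used for log2 CPM. Fitted folds of genes near 0 depend on the prior. For such genes pooled counts, ratios with 95% exact counting intervals or a floor of 3 counts over the group are given, which cover counting error only. Depth ran from 12832988 to 18077963 counts, and the median SE of a log2 fold change was 0.14.

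Of 41 gene lists, 40 with at least 5 tested members were tested with limma 3.58.1's camera (preset correlation 0.01, two-sided, adjusted over the lists within a comparison). The other holds Y-linked genes, which were read per library. Camera with an estimated correlation and fry were run beside it. Tested members not counted as rising or falling did not pass edgeR's test. The groups, gene lists, model, rule for named genes and most alternatives were chosen before the data were examined. Named genes were the 8 largest rises and falls past the threshold per comparison at a mean of 1 CPM or more without overlap between the libraries of the groups. To these came up to 4 members with the smallest p of each list past its test or with 3 changed members, up to 2 of other lists, 12 genes fixed in advance and the 6 shared genes of largest mean fold. Where 0 genes passed, the 6 with the smallest p were named. Names without a gene symbol were left out. The rule, with genes added outside it, gave 279 genes, of which the text prints a part, 121 genes, chosen for space after their values were seen. Malat1, Ifi202b, Ang2, Gm10260, Gm10503, Prm1, Prm2 and Tnp2 lie outside the rule and were chosen after their values were seen.

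Alternatives were DESeq2 1.42.0, limma-voom, edgeR without legacy mode, other scalings, other filters, the compared groups alone, a 2-fold minimum, title codes summed or as a correlation block, a Y-linked covariate and each library left out. Added after seeing the data were fits with GC and length offsets (15514 genes with a value), fits of the libraries with or without Y-linked reads, a fit without 2 libraries with spermatid transcripts, counts without genes sharing 20% of their 50-mers, and the imprinted lists with Ampd3 counted as maternally expressed. Gene copies were found by 50-mers shared between transcripts of 55450 annotated genes. Genes sharing reads with copies are uncertain, as are antisense pairs while the strand setting is unknown. Replicate pairs differed by more than sampling noise, with chi-square over degrees of freedom from 7.94 to 65.0, so none was merged.

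The chance correlation of comparisons that share controls came from 20 simulations of unchanged groups. A first version took the control means as the true levels, which removed the controls' own error. It was corrected after its output was seen. The test was checked on simulated data for ICSI-F1 against control with 15324 genes. It recovered 31 of 67 genes changed 1.5-fold (46.3%), 44 of 67 changed 2-fold (65.7%) and 53 of 66 changed 3-fold (80.3%). Spongiotrophoblast list genes had also been raised 1.5-fold, and of 147 calls in all 8 were of genes left unchanged (5.44%). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots.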

Results

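Mouse placentae at E19.5, shortly before birth, were profiled by stranded mRNA sequencing in 3 groups of 4 libraries each. The ICSI-F1 group held placentae of conceptuses made by intracytoplasmic sperm injection (ICSI), in which a single sperm is injected into an oocyte. The ICSI-F2 group held placentae sired by ICSI-F1 males, through in vitro fertilisation per the sample labels and through natural mating per the series description. The control group held placentae after natural mating. All libraries were labelled C57BL/6, an inbred strain. Totals ran from 12832988 to 18077963 counts per library, and 15521 genes were tested. The labels do not say that the libraries come from separate animals, so p-values measure the spread between these samples. No title code occurred in 2 groups. A factor shared by the libraries of a group, such as a preparation day, cannot be told apart from it. Values are normalised counts (CPM) as mean ± SD (n = 4 libraries). Log2 fold changes (log2FC) are given ± SE with adjusted p from edgeR's quasi-likelihood test, and genes said to rise or fall had an adjusted p under 0.05. The leading principal component held 34.5% of the variance. On it the controls lay between -50.5 and -31.2 and the 8 ICSI libraries between 11.9 and 27.5.

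The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty and the X-inactivation transcript Xist were read in each library, since the labels give no sex of the conceptus. Each group held 2 libraries with Y-linked reads and 2 without, and in controls each pair shared 1 title code, so there sex and code cannot be told apart. Summed Y-linked CPM lay between 117 and 154 in the 6 libraries with Y-linked reads, and between 0 and 1.46 in the other 6. Xist lay between 1329 and 1963 CPM in the libraries without Y-linked reads. In those with Y-linked reads Xist was 361 and 269 CPM in the controls, against 83.0 to 112 CPM in the 4 ICSI libraries.

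**Figure D1:**
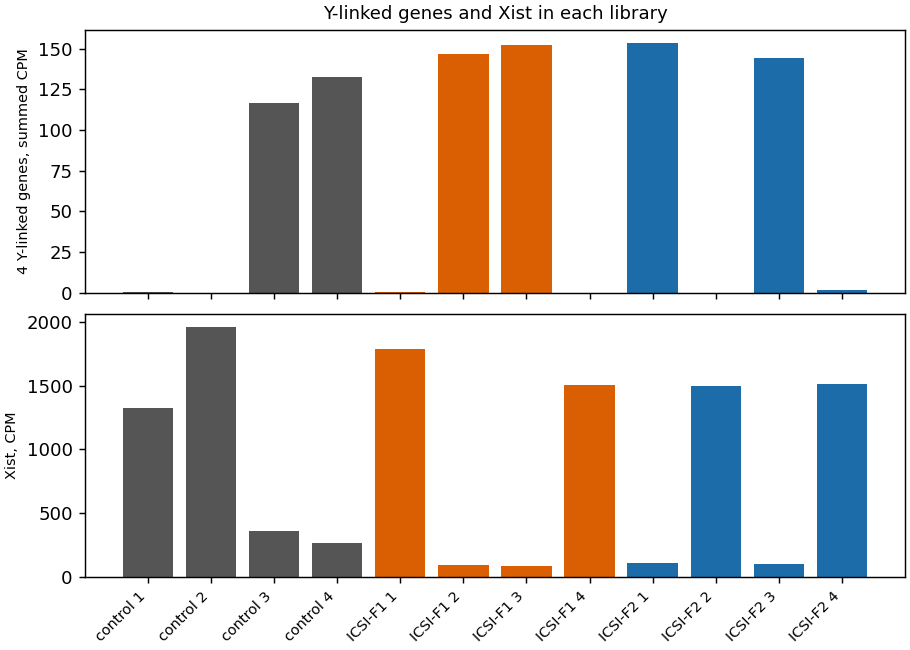
Summed CPM of 4 Y-linked genes (top) and CPM of Xist (bottom) in each of the 12 libraries, as bars coloured by group. Each group holds 2 libraries with Y-linked reads, and among these Xist is 361 and 269 CPM in controls and at most 112 CPM in ICSI libraries.

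The comparison of ICSI-F1 with control asked how placentae after ICSI differed from those after natural mating. In ICSI-F1, of 8 tested uterine NK and T cell genes (17 listed) 0 rose and 7 fell (adjusted p = 0.049 with an estimated correlation). Further, of 32 maternally expressed imprinted genes 0 rose and 11 fell, and of 24 immediate early genes 13 rose and 1 fell (adjusted p = 0.026 and 0.0013 with an estimated correlation). Cryab, a small heat shock protein gene (mm10 chromosome 9, 50751325 to 50756636), fell from 316 ± 25.4 to 63.7 ± 11.7 CPM (log2FC -2.31 ± 0.16). Tpbpa, the classical spongiotrophoblast marker (mm10 chromosome 13, 60938492 to 60941984), rose from 4063 ± 848 to 8049 ± 535 CPM (log2FC 0.99 ± 0.14). In all, 2988 of 15521 genes (19.3%) changed, 1399 upward and 1589 downward, and 677 of these changed at least 2-fold. The ICSI-F1 and control libraries did not overlap for 23.2% of all tested genes, against a chance share of 2.86%.

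Of 18 decidua genes 1 rose, 8 fell and 9 did not pass, with 1 up and 11 down adjusted over the list alone (median log2FC -0.89, camera adjusted p = 4.3e-07, adjusted p = 0.327 with an estimated correlation). Prl8a2, the decidual prolactin-related protein, fell from 837 ± 51.5 to 339 ± 127 CPM (adjusted p = 0.0042). The serine protease gene Htra3 fell from 627 ± 155 to 202 ± 107 CPM (adjusted p = 0.0089). Of 8 NK and T cell genes 0 rose, 7 fell and 1 did not pass, also adjusted over the list alone (median log2FC -5.29, camera adjusted p = 2.9e-15, adjusted p = 0.049 with an estimated correlation). With Gzmb set to the floor of 3 ICSI-F1 reads, that median was -4.91. The genes of granzymes, serine proteases of cytotoxic granules, and of perforin fell to levels near 0. Gzmd went from 15.9 ± 7.52 to 0.226 ± 0.102 CPM and Prf1 from 4.09 ± 1.91 to 0.185 ± 0.110 CPM. Gzmb had 70 control reads and 1 ICSI-F1 read, a ratio of 72.8 with a 95% counting interval of 12.6 to 2917, or at least 18.7-fold without ICSI-F1 replicate 3. Gzmd shares 21.7% of its 50-mers with other genes, so its level is uncertain. Of 16 stroma and pericyte genes 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.203). The proteoglycan genes Lum and Dcn fell (log2FC -3.10 ± 0.39 and -2.53 ± 0.40). Beside these groups, Xist in the libraries with Y-linked reads averaged 89.6 CPM in ICSI-F1 and 315 CPM in control.

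Of 26 spongiotrophoblast genes 12 rose, 1 fell and 13 did not pass, with 14 up and 1 down adjusted over the list alone (median log2FC 0.63, camera adjusted p = 8.5e-10, adjusted p = 0.334 with an estimated correlation). Prl3a1, a prolactin family gene, rose from 323 ± 61.5 to 939.9 ± 71.5 CPM. Prl3b1, the placental lactogen II gene, rose from 6772 ± 428 to 11458 ± 1180.4 CPM, and Ceacam13 from 367 ± 77.1 to 782 ± 45.9 CPM. The member that fell was Psg22, a pregnancy-specific glycoprotein gene (log2FC -0.90 ± 0.11). Of 19 giant cell genes 8 rose, 0 fell and 11 did not pass, with 11 up and 0 down adjusted over the list alone (median log2FC 0.44, camera adjusted p = 3.5e-06, adjusted p = 0.147 with an estimated correlation). The X-linked homeobox gene Rhox6 rose (log2FC 0.47 ± 0.06). The cathepsin gene Ctsm, which shares 25.5% of its 50-mers with other genes, also rose (log2FC 1.24 ± 0.20). Of 11 syncytiotrophoblast layer II genes 0 rose, 5 fell and 6 did not pass, with 0 up and 6 down adjusted over the list alone (median log2FC -0.61, camera adjusted p = 0.0029, adjusted p = 0.334 with an estimated correlation). This layer is the fetal-facing part of the exchange barrier. Vegfa, the vascular endothelial growth factor gene, fell from 139 ± 23 to 82.6 ± 5.91 CPM. The sulfate transporter gene Slc13a4 fell from 174 ± 26 to 74.6 ± 11.3 CPM (adjusted p = 0.029). Each library was left out in turn, and ranges of adjusted p are over these 12 fits for genes and over all 21 alternatives for lists (22 for imprinted lists) where no other number is given. The Slc13a4 call ended without control replicate 1 (adjusted p = 0.0620), 2 (0.0673), ICSI-F1 replicate 1 (0.0658), 2 (0.0772), 3 (0.0542) or 4 (0.0567), range 0.00263 to 0.0772. The glucagon receptor gene Gcgr fell from 21.5 ± 6.89 to 9.1 ± 2.49 CPM (adjusted p = 0.031). The Gcgr call ended without control replicate 1 (adjusted p = 0.0763), 2 (0.0590), ICSI-F1 replicate 1 (0.0622), 2 (0.0881) or 3 (0.0643), range 0.0136 to 0.0881.

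Of 9 syncytiotrophoblast layer I genes 0 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.064). The transferrin receptor gene Tfrc fell from 1391 ± 321 to 330.1 ± 79.9 CPM (adjusted p = 0.012), and Lgals3 fell (log2FC -0.36 ± 0.06). Of 11 glycogen trophoblast genes 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.889). The prolactin family gene Prl2a1 rose (log2FC 1.12 ± 0.19). The glycogen synthase gene Gys1 and the mRNA-binding protein gene Igf2bp2 fell (log2FC -0.55 ± 0.09 and -0.71 ± 0.12). Of 10 labyrinth progenitor genes 1 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.889). The fall was Tead4, a transcription factor of early trophoblast (log2FC -0.57 ± 0.07).

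Imprinted genes are expressed from a single parental allele. Of 32 maternally expressed imprinted genes 0 rose, 11 fell and 21 did not pass, also adjusted over the list alone (median log2FC -0.42, camera adjusted p = 7.6e-07, adjusted p = 0.026 with an estimated correlation). Non-coding RNAs of the Dlk1-Dio3 cluster fell. Meg3 (ENSMUSG00000021268, mm10 chromosome 12, 109541001 to 109571726) went from 472 ± 34 to 230.0 ± 17.9 CPM (adjusted p = 9.7e-05). Rian went from 450.1 ± 29.9 to 276 ± 34.7 CPM and Mirg from 65.9 ± 6.1 to 33.1 ± 5.16 CPM. The protease inhibitor gene Tfpi2 fell from 871 ± 275 to 170.0 ± 72.6 CPM (log2FC -2.36 ± 0.33). Of 24 paternally expressed imprinted genes 0 rose, 7 fell and 17 did not pass, with 0 up and 10 down adjusted over the list alone (median log2FC -0.24, camera adjusted p = 0.0024, adjusted p = 0.44 with an estimated correlation). Rtl1 (mm10 chromosome 12, 109589193 to 109600330), a retrotransposon-derived gene of the same cluster, fell from 79.7 ± 5.08 to 39.7 ± 4.45 CPM (adjusted p = 0.0012). Its antisense transcript comes from the maternal allele, and the strand setting of the counting is not given. Necdin (Ndn) fell (log2FC -0.52 ± 0.11), as did the non-coding Peg13 (log2FC -0.55 ± 0.10). The AMP deaminase gene Ampd3, also in this list though known as maternally expressed in mouse placenta, fell (log2FC -1.67 ± 0.33). With it counted as maternally expressed, 12 of 33 maternally and 6 of 23 paternally expressed genes fell, and both lists still passed camera. Beside both lists, the decidua median was -0.89, with Xist as given above.

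Of 11 H3K27me3-dependent imprinted genes 3 rose and 2 fell, with 3 up and 3 down adjusted over the list alone (camera adjusted p = 0.889). The amino acid transporter gene Slc38a4 rose from 849.6 ± 116 to 1158 ± 29 CPM. The matricellular gene Smoc1 rose (log2FC 1.33 ± 0.19) and the sterol transfer gene Gramd1b fell (log2FC -1.37 ± 0.19). The polycomb-related gene Sfmbt2 rose (log2FC 0.30 ± 0.08, adjusted p = 0.025). The Sfmbt2 call ended without control replicate 1 (adjusted p = 0.0607), ICSI-F1 replicate 1 (0.0562) or 2 (0.0536), range 0.0144 to 0.0607. The adaptor gene Gab1 had a log2FC of 0.02 ± 0.07 (adjusted p = 0.841) and the fetal growth factor gene Igf2 of -0.03 ± 0.12 (0.884). Igf2 shares 75.9% of its 50-mers with another gene model, so its level is uncertain. The values were -0.14 ± 0.15 for the non-coding H19 (adjusted p = 0.542), -0.05 ± 0.29 for Phlda2 (0.917) and -0.23 ± 0.12 for Peg10 (0.191). The cell cycle inhibitor gene Cdkn1c had a log2FC of -0.18 ± 0.08 (adjusted p = 0.11). It passed without control replicate 3 (adjusted p = 0.0471), range 0.0471 to 0.272.

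Of 15 fetal endothelium genes 0 rose, 3 fell and 12 did not pass, also adjusted over the list alone (median log2FC -0.25, camera adjusted p = 0.014, adjusted p = 0.571 with an estimated correlation). The endothelial receptor gene Robo4 and Kdr, the main VEGF receptor gene, fell (log2FC -0.97 ± 0.15 and -1.18 ± 0.26). The fetal endothelium call ended without ICSI-F1 replicate 4 (adjusted p = 0.0910) or in libraries without Y-linked reads (0.0825), range 7.85e-04 to 0.571. Of 26 angiogenic factor genes 2 rose, 6 fell and 18 did not pass, with 2 up and 7 down adjusted over the list alone (median log2FC -0.37, camera adjusted p = 0.04, adjusted p = 0.334 with an estimated correlation). The endothelin receptor gene Ednra fell (log2FC -1.20 ± 0.19). The natriuretic peptide gene Nppb rose from 13.8 ± 8.38 to 67.3 ± 5.36 CPM (adjusted p = 0.0083). The angiogenic factor call ended without ICSI-F1 replicate 3 (adjusted p = 0.0512), 4 (0.0910), ICSI-F2 replicate 1 (0.0597), with the Y-linked covariate (0.0639) or in libraries without Y-linked reads (0.0933), range 0.00229 to 0.334. Of 35 nutrient transporter genes 1 rose, 12 fell and 22 did not pass, with 1 up and 14 down adjusted over the list alone (median log2FC -0.37, camera adjusted p = 8.2e-04, adjusted p = 0.445 with an estimated correlation). The glucose transporter gene Slc2a3 and the cationic amino acid transporter gene Slc7a1 fell (log2FC -1.24 ± 0.18 and -0.71 ± 0.15).

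Of 15 macrophage genes 7 rose, 1 fell and 7 did not pass, with 8 up and 3 down adjusted over the list alone (median log2FC 0.88, camera adjusted p = 0.0017, adjusted p = 0.334 with an estimated correlation). Lysozyme Lyz2 rose from 29.4 ± 6.85 to 160.2 ± 19.95 CPM and the complement gene C1qa from 5.97 ± 2.04 to 15.6 ± 3.75 CPM. Of 10 neutrophil genes 5 rose, 1 fell and 4 did not pass, also adjusted over the list alone (median log2FC 0.73, camera adjusted p = 0.024, adjusted p = 0.334 with an estimated correlation). The calprotectin subunit S100a9 rose (log2FC 1.36 ± 0.29) and S100a8 fell (log2FC -0.83 ± 0.17). The neutrophil call ended without control replicate 2 (adjusted p = 0.0635), ICSI-F1 replicate 4 (0.0565) or in libraries with Y-linked reads (0.0512), range 0.00620 to 0.334. Of 23 inflammation genes 5 rose, 2 fell and 16 did not pass, also adjusted over the list alone (median log2FC 0.47, camera adjusted p = 0.018, adjusted p = 0.334 with an estimated correlation). The cytokine gene Il1b rose from 1.42 ± 0.272 to 8.78 ± 1.92 CPM (adjusted p = 1.9e-04). Its decoy receptor gene Il1r2 and the adhesion molecule gene Icam1 fell (log2FC -1.68 ± 0.23 and -0.66 ± 0.10).

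Of 16 MHC and antigen presentation genes 0 rose, 6 fell and 10 did not pass, also adjusted over the list alone (median log2FC -0.28, camera adjusted p = 0.0024, adjusted p = 0.519 with an estimated correlation). The class I genes B2m, from 437 ± 85.6 to 232 ± 28.9 CPM, and H2-K1 (log2FC -0.62 ± 0.15) fell. Of 35 interferon response genes 3 rose, 0 fell and 32 did not pass, also adjusted over the list alone (median log2FC 0.12, camera adjusted p = 0.031, adjusted p = 0.65 with an estimated correlation). Ifi27l2a was among those that rose (log2FC 1.80 ± 0.31). The interferon response call ended without control replicate 1 (adjusted p = 0.0543), 2 (0.335), ICSI-F1 replicate 1 (0.0519), 4 (0.0907) or without the 2 libraries with most spermatid reads (0.0598), range 4.86e-07 to 0.650. The direction turned in libraries with Y-linked reads (0.619).

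Of 24 immediate early genes 13 rose, 1 fell and 10 did not pass, with 14 up and 1 down adjusted over the list alone (median log2FC 0.35, camera adjusted p = 1.1e-10, adjusted p = 0.0013 with an estimated correlation). Immediate early genes are induced within minutes of a stimulus. Egr1 (mm10 chromosome 18, 34859823 to 34864984) rose from 9.34 ± 1.32 to 38.1 ± 3.28 CPM (adjusted p = 1.6e-05) and Jun from 121 ± 5.04 to 204 ± 16 CPM. Ier2 rose from 11.1 ± 0.771 to 23.1 ± 2.35 CPM and Fosb from 10.7 ± 4.08 to 60.8 ± 10.8 CPM. Of 15 heat shock genes 8 rose, 2 fell and 5 did not pass, with 11 up and 2 down adjusted over the list alone (median log2FC 0.28, camera adjusted p = 0.0063, adjusted p = 0.445 with an estimated correlation). The co-chaperone gene Dnaja1 rose (log2FC 0.43 ± 0.06), and so did Hspa1b, which shares 62.3% of its 50-mers with other genes (log2FC 0.74 ± 0.09). Cryab, also in this list, fell. Of 32 oxidative phosphorylation genes 13 rose, 0 fell and 19 did not pass, with 19 up and 1 down adjusted over the list alone (median log2FC 0.21, camera adjusted p = 3.8e-06, adjusted p = 0.334 with an estimated correlation). GC and length offsets moved that median to 0.14. The ATP synthase gene Atp5c1 rose (log2FC 0.32 ± 0.06). The complex III gene Uqcrb rose (log2FC 0.45 ± 0.08, adjusted p = 0.0034) but did not pass with GC and length offsets (adjusted p = 0.0899, range 3.8e-05 to 0.0899 in 27 alternatives). The nuclear RNA Malat1 took 2.18 ± 0.363% of counts in control and 1.26 ± 0.252% in ICSI-F1 libraries (two-sided exact permutation p = 0.0286). Genes of rRNA-like annotation took 2.90 ± 0.160% and 3.48 ± 0.405% (exact permutation p = 0.0571).

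The 8 largest rises in ICSI-F1, among genes past the test with a mean of at least 1 CPM and no overlap of libraries, were Eno1b, Tmem114, Rgs1, Tmprss11e, Ccl9, Il1b, Fosb and Arg1. Eno1b, which shares 84.5% of its 50-mers with other genes, rose from 0.0649 ± 0.0934 to 2.74 ± 0.482 CPM. Rgs1, a regulator of G-protein signalling, rose from 1.51 ± 0.556 to 11.7 ± 1.96 CPM (adjusted p = 7.1e-04). The chemokine gene Ccl9 rose from 1.56 ± 0.516 to 9.65 ± 3.0 CPM (adjusted p = 0.0029). Tmem114 and Tmprss11e rose by 3.05 ± 0.70 and 2.71 ± 0.67 on the log2 scale. Rnase2a, with 2 control and 813 ICSI-F1 reads, missed the test (adjusted p = 0.06). The arginase gene Arg1 rose (log2FC 2.46 ± 0.65, adjusted p = 0.026). The Arg1 call ended without control replicate 2 (adjusted p = 0.0686), 3 (0.0631), 4 (0.0639), ICSI-F1 replicate 3 (0.0545) or 4 (0.0581), range 0.00391 to 0.0686. The 8 largest falls were Inmt, mt-Nd3, Gzmd, Gzmf, Gzmc, Gzmg, Prf1 and the chondromodulin gene Cnmd. Inmt, an N-methyltransferase gene (mm10 chromosome 6, 55170626 to 55175043), had 576 control reads and 3 ICSI-F1 reads. The ratio was 199.7 with a 95% counting interval of 68.0 to 971, and without ICSI-F1 replicate 4, which held the 3 reads, the fall was at least 143.5-fold. The mitochondrial gene mt-Nd3 went from 12.7 ± 3.17 to 0.179 ± 0.0825 CPM, but 98% of its 50-mers are shared with other genes.

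**Figure D2:**
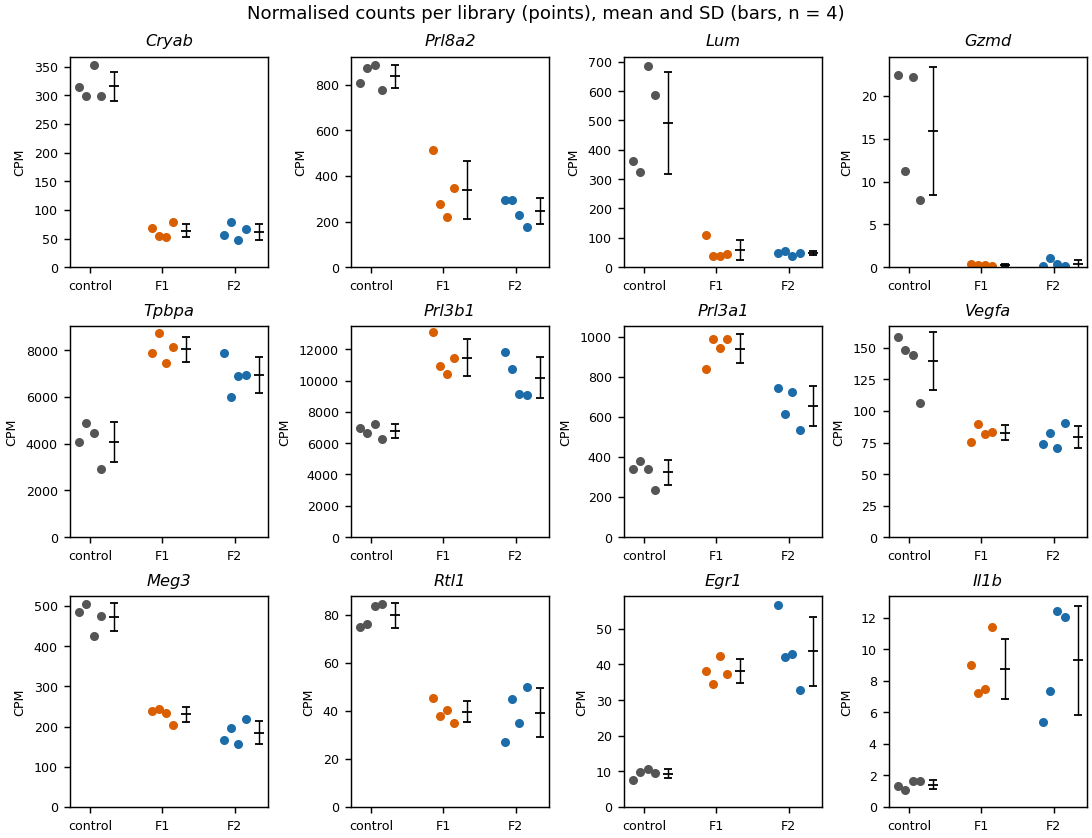
CPM of 12 genes in each library (points, grouped as control, ICSI-F1 and ICSI-F2), with the mean and SD of the 4 libraries as bars beside them. Cryab averages 316 CPM in control and 62 in ICSI-F2, and Egr1 9.34 and 43.6.

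Of 19 yolk sac endoderm genes 0 rose and 1 fell, with 0 up and 0 down adjusted over the list alone (camera adjusted p = 0.203). The fall was Rbp4, the retinol-binding protein gene (log2FC -1.19 ± 0.37, adjusted p = 0.047). The Rbp4 call ended without control replicate 1 (adjusted p = 0.0947), 2 (0.0764), 3 (0.0908), 4 (0.0731), ICSI-F1 replicate 1 (0.0775), 2 (0.119), 3 (0.0645), 4 (0.107), ICSI-F2 replicate 3 (0.0634) or 4 (0.0580), range 0.00515 to 0.119. For the lists from erythroid to keratinocyte, counts adjusted over the list alone were the same where not given. Of 14 erythroid genes 1 rose and 0 fell (camera adjusted p = 0.821). Of 28 extracellular matrix genes 4 rose and 5 fell, with 5 up and 7 down adjusted over the list alone (camera adjusted p = 0.776). Of 22 cholesterol synthesis genes 0 rose and 2 fell (camera adjusted p = 0.24). Of 28 DNA methylation and chromatin genes 6 rose and 1 fell, with 7 up and 3 down adjusted over the list alone (camera adjusted p = 0.127). Of 30 complement and coagulation genes 1 rose and 5 fell, with 2 up and 5 down adjusted over the list alone (camera adjusted p = 0.282). Of 29 unfolded protein response genes 4 rose and 2 fell (camera adjusted p = 0.061). Of 33 cell cycle genes 1 rose and 0 fell (camera adjusted p = 0.064). Of 24 glycolysis and glycogen genes 0 rose and 3 fell (camera adjusted p = 0.191). Of 23 replication-dependent histone genes 3 rose and 0 fell (camera adjusted p = 0.106). Of 11 mitochondrially encoded genes 3 rose and 1 fell (camera adjusted p = 0.889). Of 6 amnion and keratinocyte genes 0 rose and 0 fell (camera adjusted p = 0.776). Among lists that did not pass, median, mean and test differed in sign (test, median, mean) for H3K27me3-dependent imprinted (upward, -0.07, -0.06), glycogen trophoblast (downward, -0.04, 0.01), labyrinth progenitor (downward, 0.09, -0.06), erythroid (upward, -0.10, -0.03), amnion and keratinocyte (upward, 0.21, -0.03), mitochondrially encoded (upward, 0.12, -0.34) and germline (upward, -0.02, -0.16).

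Of 40 lists tested, 18 passed in ICSI-F1, 9 upward and 9 downward. With an estimated correlation 3 held, namely maternally expressed imprinted, NK and T cell, and immediate early genes. The gene count fell to 797 when libraries sharing a title code were summed, to 1918 with limma-voom and a correlation within codes, to 1532 in the libraries without Y-linked reads and to 1916 without ICSI-F1 replicate 2. Beside list calls given above, the libraries with Y-linked reads ended those of heat shock response, inflammation, nutrient transporters and syncytiotrophoblast layer II (adjusted p from 0.0512 to 0.646). Summing title codes ended 27 calls of genes named in the text, Adamts1, Ampd3, Arg1, Atp5c1, Ccl9, Cyp11a1, Dppa3, Fdps, Fdx1, Gcgr, H2-K1, Htra3, Kdr, Nppb, Peg13, Plvap, Prl8a2, Rbp4, S100a8, S100a9, Slc13a4, Slc7a1, Taf7l, Tfrc, Tmem114, Tmprss11e and Trim28 (adjusted p from 0.0524 to 0.192). Limma-voom, other filters, scalings or subsets of libraries, or GC and length offsets, leaving out 1 library aside, ended 9, Arg1, Dppa3, Fdps, Gcgr, Plvap, Rbp4, Sfmbt2, Slc13a4 and Uqcrb (adjusted p from 0.0512 to 0.125). With upper-quartile factors the calls split into 1825 higher and 1385 lower, against 1399 and 1589.

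The comparison of ICSI-F2 with control cannot tell descent from ICSI-F1 males apart from in vitro fertilisation, where used. In ICSI-F2, of 8 uterine NK and T cell genes 0 rose and 7 fell (adjusted p = 0.063 with an estimated correlation). Further, of 32 maternally expressed imprinted genes 0 rose and 14 fell, and of 24 immediate early genes 12 rose and 1 fell (adjusted p = 0.0095 and 0.0014 with an estimated correlation). Cryab stood at 62 ± 14.1 CPM against 316 ± 25.4 in control (log2FC -2.35 ± 0.16), and Egr1 at 43.6 ± 9.79 CPM against 9.34 ± 1.32 (log2FC 2.22 ± 0.15). In all, 3325 of 15521 genes (21.4%) changed, 1547 upward and 1778 downward, with 809 changed at least 2-fold.

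Of 18 decidua genes 1 rose, 9 fell and 8 did not pass, with 1 up and 11 down adjusted over the list alone (median log2FC -0.78, camera adjusted p = 3.5e-07, adjusted p = 0.275 with an estimated correlation). Prl8a2 stood at 248 ± 56.7 CPM (log2FC -1.76 ± 0.24) and Htra3 at 174 ± 25.4 CPM (log2FC -1.85 ± 0.34). Of 8 NK and T cell genes 0 rose, 7 fell and 1 did not pass, with 1 up and 7 down adjusted over the list alone (median log2FC -3.78, camera adjusted p = 1.6e-10, adjusted p = 0.063 with an estimated correlation). Gzmc fell from 7.31 ± 2.85 to 0.0701 ± 0.0836 CPM, Gzmf from 23 ± 9.84 to 0.804 ± 0.763 CPM and Gzmg from 15 ± 6.37 to 0.744 ± 0.479 CPM. Of 16 stroma and pericyte genes 0 rose, 7 fell and 9 did not pass, with 0 up and 8 down adjusted over the list alone (median log2FC -0.37, camera adjusted p = 0.016, adjusted p = 0.358 with an estimated correlation). Lum stood at 47.6 ± 7.54 CPM against 490.2 ± 174 in control, and Dcn at 149.9 ± 19.4 against 1086 ± 278. In the libraries with Y-linked reads, Xist averaged 106 CPM in ICSI-F2 and 315 CPM in control.

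Of 26 spongiotrophoblast genes 9 rose, 1 fell and 16 did not pass, with 11 up and 1 down adjusted over the list alone (median log2FC 0.33, camera adjusted p = 0.0012, adjusted p = 0.57 with an estimated correlation). Tpbpa stood at 6929.8 ± 777 CPM (log2FC 0.77 ± 0.14), Prl3a1 at 653 ± 99.2 (1.02 ± 0.14) and Prl3b1 at 10187 ± 1323 (0.59 ± 0.11). Of 19 giant cell genes 8 rose, 0 fell and 11 did not pass, with 14 up and 1 down adjusted over the list alone (median log2FC 0.51, camera adjusted p = 4.5e-06, adjusted p = 0.113 with an estimated correlation). Rhox6, Rhox9, the transcription factor gene Hand1 and the cathepsin gene Cts6 rose (log2FC 0.58 ± 0.06, 0.47 ± 0.07, 0.51 ± 0.09 and 0.52 ± 0.11). Of 11 syncytiotrophoblast layer II genes 0 rose, 2 fell and 9 did not pass, with 0 up and 4 down adjusted over the list alone (median log2FC -0.52, camera adjusted p = 0.011, adjusted p = 0.358 with an estimated correlation). Vegfa and the EGF family gene Tgfa fell (log2FC -0.81 ± 0.11 and -0.65 ± 0.16). Of 9 syncytiotrophoblast layer I genes 0 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.355). Tfrc fell (log2FC -1.81 ± 0.45, adjusted p = 0.018). The Tfrc call ended without ICSI-F2 replicate 3 (adjusted p = 0.0502), range 0.00153 to 0.0502. Of 11 glycogen trophoblast genes 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.984). Of 10 labyrinth progenitor genes 2 rose and 1 fell, with 4 up and 2 down adjusted over the list alone (camera adjusted p = 0.449).

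Of 32 maternally expressed imprinted genes 0 rose, 14 fell and 18 did not pass, with 0 up and 15 down adjusted over the list alone (median log2FC -0.56, camera adjusted p = 8.5e-09, adjusted p = 0.0095 with an estimated correlation). Meg3 stood at 185 ± 28.4 CPM against 472 ± 34 in control (adjusted p = 9.5e-06), Mirg at 29.1 ± 3.39 CPM and Rian at 251 ± 33.6 CPM. Tnfrsf23, a decoy receptor gene that shares 21.8% of its 50-mers with other genes, fell (log2FC -0.86 ± 0.11). Of 24 paternally expressed imprinted genes 0 rose, 7 fell and 17 did not pass, with 1 up and 7 down adjusted over the list alone (median log2FC -0.26, camera adjusted p = 0.0047, adjusted p = 0.38 with an estimated correlation). Rtl1, Ndn and Mest fell (log2FC -1.02 ± 0.15, -0.74 ± 0.11 and -0.69 ± 0.13). With Ampd3 counted as maternally expressed, 15 of 33 maternally and 6 of 23 paternally expressed genes fell, and both lists still passed camera. Beside them the decidua median was -0.78, with Xist as given above. Of 11 H3K27me3-dependent imprinted genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.463). Sfmbt2 and Slc38a4 rose (log2FC 0.45 ± 0.08 and 0.44 ± 0.10), and Gramd1b fell (-1.46 ± 0.19). Gab1 rose (log2FC 0.26 ± 0.07, adjusted p = 0.02). The Gab1 call ended without ICSI-F2 replicate 1 (adjusted p = 0.0513), range 0.0177 to 0.0513.

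Cdkn1c fell in ICSI-F2 (log2FC -0.27 ± 0.08, adjusted p = 0.023). The Cdkn1c call ended without control replicate 1 (adjusted p = 0.0605), 2 (0.0517) or ICSI-F2 replicate 2 (0.0733), range 0.0104 to 0.0733. Igf2, whose level is uncertain through shared 50-mers, missed the threshold (log2FC -0.32 ± 0.12, adjusted p = 0.073). It passed without control replicate 2 (adjusted p = 0.0383) or ICSI-F2 replicate 3 (0.0369), range 0.0369 to 0.178. H19 (adjusted p = 0.773), Phlda2 (0.311) and Peg10 (0.677) did not pass, with log2FC of 0.07 ± 0.15, 0.42 ± 0.29 and 0.08 ± 0.12.

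Of 15 fetal endothelium genes 0 rose, 8 fell and 7 did not pass, with 0 up and 10 down adjusted over the list alone (median log2FC -0.45, camera adjusted p = 1.9e-05, adjusted p = 0.358 with an estimated correlation). Robo4, Kdr and Plvap fell (log2FC -1.10 ± 0.15, -1.48 ± 0.26 and -0.76 ± 0.14). Of 26 angiogenic factor genes 1 rose, 10 fell and 15 did not pass, with 2 up and 13 down adjusted over the list alone (median log2FC -0.62, camera adjusted p = 1.2e-04, adjusted p = 0.063 with an estimated correlation). Ednra fell (log2FC -1.64 ± 0.20). Of 14 erythroid genes 0 rose, 8 fell and 6 did not pass, with 0 up and 9 down adjusted over the list alone (median log2FC -0.94, camera adjusted p = 1.5e-04, adjusted p = 0.358 with an estimated correlation). The red cell membrane gene Gypa fell from 3.2 ± 1.21 to 0.705 ± 0.371 CPM and the ferrochelatase gene Fech from 69.8 ± 18.9 to 43.5 ± 1.92 CPM. The globin gene Hbb-bs, which shares 65.8% of its 50-mers with other genes, fell from 151 ± 93.6 to 28.3 ± 7.91 CPM. Of 19 yolk sac endoderm genes 0 rose, 3 fell and 16 did not pass, with 0 up and 2 down adjusted over the list alone (median log2FC -2.15, camera adjusted p = 5.1e-04, adjusted p = 0.57 with an estimated correlation). Rbp4 fell (log2FC -2.08 ± 0.38). Yolk sac scores (mean log2 CPM) were 0.815 and 1.52 in ICSI-F2 replicates 2 and 4, 6.07 and 4.45 in replicates 1 and 3, and 3.32 to 7.81 in controls. The direction turned in the libraries with Y-linked reads (adjusted p = 0.505, range 7.4e-59 to 0.570). Of 28 extracellular matrix genes 1 rose, 9 fell and 18 did not pass, with 3 up and 10 down adjusted over the list alone (median log2FC -0.26, camera adjusted p = 0.024, adjusted p = 0.358 with an estimated correlation). The protease genes Mmp2 and Adamts1 fell (log2FC -1.51 ± 0.19 and -1.15 ± 0.17). The extracellular matrix call ended without ICSI-F2 replicate 2 (adjusted p = 0.0525), 4 (0.0705), in libraries without Y-linked reads (0.146) or with GC and length offsets (0.0983), range 0.00119 to 0.358. The offsets moved the median from -0.264 to -0.20.

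Of 35 nutrient transporter genes 1 rose, 7 fell and 27 did not pass, with 1 up and 12 down adjusted over the list alone (median log2FC -0.35, camera adjusted p = 0.0022, adjusted p = 0.471 with an estimated correlation). Of 32 oxidative phosphorylation genes 13 rose, 0 fell and 19 did not pass, with 19 up and 0 down adjusted over the list alone (median log2FC 0.20, camera adjusted p = 2.0e-05, adjusted p = 0.358 with an estimated correlation). Of 22 cholesterol synthesis genes 0 rose, 4 fell and 18 did not pass, also adjusted over the list alone (median log2FC -0.35, camera adjusted p = 0.024, adjusted p = 0.592 with an estimated correlation). Dhcr7 and Fdps fell (log2FC -0.86 ± 0.15 and -0.99 ± 0.22). Cholesterol synthesis scores were 5.36, 4.96, 4.22 and 4.49 in controls 1 to 4 and 4.19 to 4.48 in ICSI-F2, and controls 1 and 2 also had the highest yolk sac scores (7.81 and 6.77). The cholesterol synthesis call ended without control replicate 1 (adjusted p = 0.245), 2 (0.0810), ICSI-F2 replicate 2 (0.0600), 4 (0.0570) or without the 2 libraries with most spermatid reads (0.0704), range 4.12e-11 to 0.592. The direction turned in libraries with Y-linked reads (0.310). Of 28 DNA methylation and chromatin genes 7 rose, 1 fell and 20 did not pass, also adjusted over the list alone (median log2FC 0.13, camera adjusted p = 0.043, adjusted p = 0.275 with an estimated correlation). The corepressor gene Trim28 and the histone demethylase gene Kdm5b rose (log2FC 0.35 ± 0.07 and 0.24 ± 0.06). The chromatin list call ended without control replicate 1 (adjusted p = 0.0625), 3 (0.0825), ICSI-F2 replicate 2 (0.0600), 3 (0.0508), in libraries with Y-linked reads (0.113) or in libraries without Y-linked reads (0.116), range 0.00126 to 0.275.

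Of 24 immediate early genes 12 rose, 1 fell and 11 did not pass, with 15 up and 1 down adjusted over the list alone (median log2FC 0.40, camera adjusted p = 2.5e-10, adjusted p = 0.0014 with an estimated correlation). Of 15 heat shock genes 12 rose, 2 fell and 1 did not pass, also adjusted over the list alone (median log2FC 0.36, camera adjusted p = 4.0e-05, adjusted p = 0.278 with an estimated correlation). Dnaja1 and Hspa1b rose (log2FC 0.46 ± 0.06 and 0.95 ± 0.09) and Cryab fell. Of 23 inflammation genes 9 rose, 2 fell and 12 did not pass, with 9 up and 3 down adjusted over the list alone (median log2FC 0.42, camera adjusted p = 0.016, adjusted p = 0.358 with an estimated correlation). Of 10 neutrophil genes 4 rose, 1 fell and 5 did not pass, also adjusted over the list alone (median log2FC 0.58, camera adjusted p = 0.019, adjusted p = 0.358 with an estimated correlation). The neutrophil call ended without control replicate 2 (adjusted p = 0.0522), range 0.00601 to 0.358. Of 16 MHC and antigen presentation genes 1 rose, 6 fell and 9 did not pass, with 3 up and 6 down adjusted over the list alone (median log2FC -0.18, camera adjusted p = 0.013, adjusted p = 0.57 with an estimated correlation). The MHC list call ended without ICSI-F2 replicate 2 (adjusted p = 0.101), 4 (0.0729), in libraries with Y-linked reads (0.356) or without the 2 libraries with most spermatid reads (0.0762), range 2.74e-04 to 0.570. Of 15 macrophage genes 3 rose and 2 fell, with 4 up and 3 down adjusted over the list alone (camera adjusted p = 0.157). Lyz2 and Adgre1, the F4/80 antigen gene, rose (log2FC 1.72 ± 0.30 and 0.89 ± 0.23). Malat1 took 1.30 ± 0.155% and rRNA-like genes 3.56 ± 0.158% of ICSI-F2 counts, and both differed from control (exact permutation p = 0.0286 each).

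Among genes of the same limits, the 8 largest rises in ICSI-F2 were Rnase2a, Eno1b, Tpm3-rs7, Cxcl2, Ccl3, Nefm, Tmprss11e and Il1b. Rnase2a, an eosinophil-associated ribonuclease gene (mm10 chromosome 14, 51255262 to 51256112), had 2 control reads and 1179 ICSI-F2 reads. The ratio was 566 with a 95% counting interval of 156 to 4675 (adjusted p = 0.043). It was 303 without ICSI-F2 replicate 4 and 853 without control replicate 2. The Rnase2a call ended without control replicate 1 (adjusted p = 0.0975), 2 (0.0969), 3 (0.0957), 4 (0.0977), ICSI-F1 replicate 4 (0.0526), ICSI-F2 replicate 1 (0.0750) or 4 (0.0759), range 0.0108 to 0.0977. Tpm3-rs7, a tropomyosin copy that shares 21.7% of its 50-mers with other genes, rose (log2FC 3.72 ± 1.11, adjusted p = 0.036). The Tpm3-rs7 call ended without control replicate 1 (adjusted p = 0.0864), 2 (0.0763), 3 (0.0704), 4 (0.0776), ICSI-F2 replicate 1 (0.0840), 2 (0.0638) or 3 (0.0593), range 0.00810 to 0.0864. The chemokine genes Cxcl2 and Ccl3 rose (log2FC 3.15 ± 0.73 and 2.92 ± 0.55), and so did the neurofilament gene Nefm (log2FC 2.80 ± 0.53). The Cxcl2 call ended with title codes summed (adjusted p = 0.0726) or as a correlation block (0.0739), range 1.6e-04 to 0.0739 in 27 alternatives. The 8 largest falls were Inmt, Gzmc, mt-Nd3, Gzmd, Gzmf, Ctsk, Cnmd and Gzmg. Inmt had 0 reads in ICSI-F2 and was at least 200.1-fold lower, against a floor of 3 counts over the group. The cathepsin gene Ctsk fell from 388 ± 99.8 to 16.5 ± 18.4 CPM (adjusted p = 0.018). The Ctsk call ended without ICSI-F2 replicate 3 (adjusted p = 0.0530), range 0.0134 to 0.0530.

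**Figure D3:**
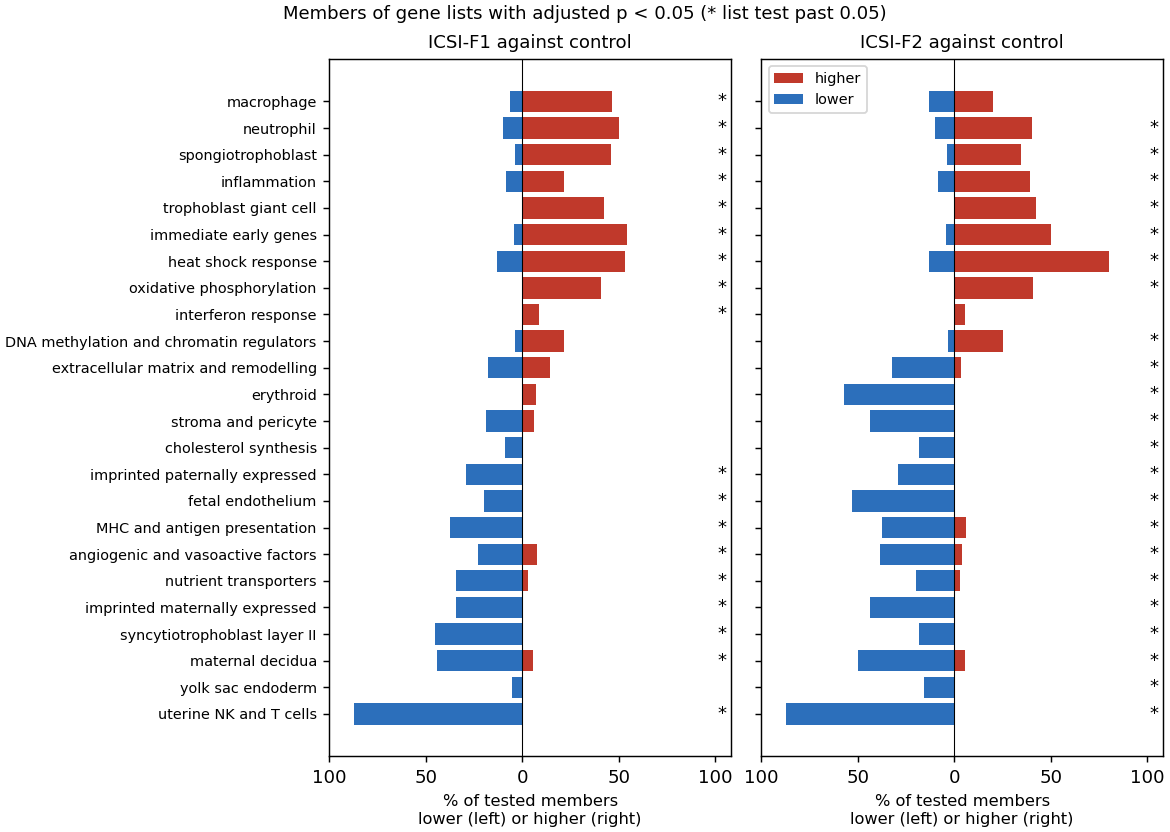
Share of the tested members of each list that passed edgeR's adjusted p threshold of 0.05, higher (right) or lower (left), in ICSI-F1 (left panel) and ICSI-F2 (right panel) against control, with an asterisk where the camera list test passed with its preset correlation. Of 8 uterine NK and T cell genes 7 are lower in each comparison.

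For the lists from interferon response to keratinocyte, counts adjusted over the list alone were the same where not given. Of 35 interferon response genes 2 rose and 0 fell, with 1 up and 0 down adjusted over the list alone (camera adjusted p = 0.326). Of 30 complement and coagulation genes 2 rose and 5 fell, with 3 up and 5 down adjusted over the list alone (camera adjusted p = 0.092). Of 29 unfolded protein response genes 3 rose and 2 fell (camera adjusted p = 0.749). Of 33 cell cycle genes 2 rose and 0 fell (camera adjusted p = 0.086). Of 24 glycolysis and glycogen genes 1 rose and 4 fell (camera adjusted p = 0.092). Of 23 replication-dependent histone genes 3 rose and 0 fell (camera adjusted p = 0.155). Of 11 mitochondrially encoded genes 2 rose and 1 fell, with 4 up and 1 down adjusted over the list alone (camera adjusted p = 0.463). Of 6 amnion and keratinocyte genes 0 rose and 0 fell (camera adjusted p = 0.581). In ICSI-F2, median, mean and test differed in sign (test, median, mean) for H3K27me3-dependent imprinted (upward, 0.04, -0.05), glycogen trophoblast (upward, -0.04, -0.02), syncytiotrophoblast layer I (downward, 0.03, -0.25), steroid and thyroid hormone (upward, 0.05, -0.36), unfolded protein response (upward, -0.02, -0.04), mitochondrially encoded (upward, 0.20, -0.31) and germline (upward, -0.04, -0.17), all lists that did not pass.

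In ICSI-F2, 22 of 40 lists passed, 8 upward and 14 downward. With an estimated correlation 2 held, maternally expressed imprinted and immediate early genes. The gene count fell to 1644 when libraries sharing a title code were summed, to 2210 in the libraries with Y-linked reads and to 1690 in those without. Beside list calls given above, the former ended those of erythroid, heat shock response, inflammation and nutrient transporters (adjusted p from 0.0516 to 0.303), and the latter those of fetal endothelium, paternally expressed imprinted, spongiotrophoblast and stroma and pericyte (adjusted p from 0.0850 to 0.645). In ICSI-F2 summing title codes ended 14 calls of genes named in the text, Cdkn1c, Ctsk, Cxcl2, Dppa3, Gab1, Igf2bp2, Kdm5b, Lgals3, Rnase2a, S100a8, Smoc1, Tfrc, Tmprss11e and Tpm3-rs7 (adjusted p from 0.0544 to 0.178). Those other alternatives, leaving out 1 library aside, ended 8, Cdkn1c, Cxcl2, Dppa3, Rnase2a, Tfrc, Tmprss11e, Tpm3-rs7 and Uqcrb (adjusted p from 0.0501 to 0.308).

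The comparison of ICSI-F2 with ICSI-F1 tested whether the generations differed from each other. At an adjusted p of 0.05, 0 genes passed edgeR's quasi-likelihood test, with 915 genes at an unadjusted p under 0.05 where chance gives 776. DESeq2 called 14 genes, 1 higher and 13 lower, with 948 at an unadjusted p under 0.05. By limma-voom 0 genes passed, with 949 unadjusted. The 95% interval of the difference lay within 2-fold for 12932 of 15521 genes (83.3%). The 6 named genes with the smallest p, all missing the threshold, were Gypa, Rprm, Tmcc2, Prxl2a, Tmed3 and Ube2l6. Gypa stood at 0.705 ± 0.371 CPM in ICSI-F2 and 4.03 ± 1.95 in ICSI-F1 (log2FC -2.50 ± 0.47, adjusted p = 0.659). Rprm, a p53-induced gene, stood at 0.243 ± 0.0969 and 1.12 ± 0.354 CPM (adjusted p = 0.659). Ube2l6, the ISG15-conjugating enzyme gene, stood at 9.47 ± 1.29 and 22.3 ± 8.15 CPM (adjusted p = 0.828). Tmcc2, Prxl2a and Tmed3 had log2FC of -0.48 ± 0.09, -0.78 ± 0.15 and -0.51 ± 0.10. Of these 6, DESeq2 called all but Rprm.

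At the level of lists, 14 of 40 passed camera with its preset correlation, 2 with higher and 12 with lower values in ICSI-F2. With an estimated correlation 0 lists passed, and by fry 0. Adjusted over the list alone, 8 of 14 erythroid, 2 of 32 maternally expressed imprinted and 1 of 26 angiogenic factor genes fell and 0 genes of the other 11 lists passed, against 0 genes of any list over all genes. Lower medians were found for erythroid genes (-0.98, camera adjusted p = 4.1e-21, adjusted p = 0.099 with an estimated correlation), spongiotrophoblast (-0.27, camera adjusted p = 2.2e-08, adjusted p = 0.445 with an estimated correlation) and yolk sac endoderm (-0.72, camera adjusted p = 6.1e-08, adjusted p = 0.447 with an estimated correlation). The same direction held for extracellular matrix (-0.18, camera adjusted p = 2.4e-05, adjusted p = 0.16 with an estimated correlation), fetal endothelium (-0.21, camera adjusted p = 8.1e-05, adjusted p = 0.445 with an estimated correlation) and angiogenic factors (-0.23, camera adjusted p = 9.6e-05, adjusted p = 0.099 with an estimated correlation). The median was lower, too, for macrophage genes (-0.19, camera adjusted p = 1.6e-04, adjusted p = 0.384 with an estimated correlation) and the unfolded protein response (-0.17, camera adjusted p = 7.2e-04, adjusted p = 0.445 with an estimated correlation).

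The other 6 lists past camera between the generations each lost the call when single libraries were left out. The median was higher for heat shock genes (0.12, camera adjusted p = 0.0038, adjusted p = 0.445 with an estimated correlation). The heat shock call ended without ICSI-F2 replicate 4 (adjusted p = 0.0578), in libraries with Y-linked reads (0.177), in libraries without Y-linked reads (0.0516) or without the 2 libraries with most spermatid reads (0.0567), range 5.99e-04 to 0.445. It was also higher for NK and T cell genes (0.94, camera adjusted p = 0.0055, adjusted p = 0.445 with an estimated correlation). The NK and T cell call ended without ICSI-F2 replicate 2 (adjusted p = 0.152) or in libraries with Y-linked reads (0.658), range 2.96e-04 to 0.658. Lower medians were found for stroma and pericyte genes (-0.25, camera adjusted p = 0.017, adjusted p = 0.445 with an estimated correlation) and cholesterol synthesis (-0.16, camera adjusted p = 0.022, adjusted p = 0.766 with an estimated correlation). The stroma call ended without ICSI-F1 replicate 1 (adjusted p = 0.214), 2 (0.0904), ICSI-F2 replicate 3 (0.0657), in libraries without Y-linked reads (0.220) or without the 2 libraries with most spermatid reads (0.119), range 1.44e-04 to 0.445. The cholesterol synthesis call ended without ICSI-F1 replicate 3 (adjusted p = 0.464), ICSI-F2 replicate 2 (0.0988), 4 (0.0683), with title codes summed (0.0623) or in libraries without Y-linked reads (0.229), range 0.00522 to 0.779. They were lower, too, for interferon response genes (-0.10, camera adjusted p = 0.023, adjusted p = 0.806 with an estimated correlation) and maternally expressed imprinted genes (-0.09, camera adjusted p = 0.044, adjusted p = 0.445 with an estimated correlation). The interferon response call ended without ICSI-F1 replicate 1 (adjusted p = 0.0564), 4 (0.258), ICSI-F2 replicate 1 (0.0662) or 2 (0.604), range 5.79e-04 to 0.806. The direction turned in libraries with Y-linked reads (0.339). The imprinted list call ended without control replicate 1 (adjusted p = 0.0567), 4 (0.0657), ICSI-F1 replicate 1 (0.167), 2 (0.0740), 3 (0.0585), ICSI-F2 replicate 1 (0.367), 3 (0.0788), with title codes summed (0.0848), with the Y-linked covariate (0.0655), in libraries without Y-linked reads (0.602) or without the 2 libraries with most spermatid reads (0.0567), range 0.00663 to 0.602. Among lists past no test, median, mean and test differed in sign (test, median, mean) for H3K27me3-dependent imprinted (upward, -0.01, 0.01), glycogen trophoblast (upward, -0.00417, -0.03), hypoxia response (upward, -1.15e-04, 0.02) and immediate early genes (upward, -0.01, 0.01). In the fit of the 6 libraries without Y-linked reads, 2 per group, 146 genes passed between the generations. That fit also ended the call for fetal endothelium and the unfolded protein response (adjusted p from 0.183 to 0.872), and the fit of the other 6 for yolk sac endoderm (adjusted p = 0.336). The unfolded protein response also missed it without the 2 libraries with most spermatid reads (0.0567, range 8.8e-06 to 0.445).

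Over 15521 genes, not independent replicates, Pearson's correlation of the generations' fold changes against control was 0.883, Spearman's 0.844 and the covariance 0.291. Both comparisons use the same controls. Any in vitro handling of both groups cannot be told apart from ICSI descent. In 20 simulations of unchanged groups against these controls the correlation averaged 0.510 (0.476 to 0.557) and the covariance 0.0406, a difference in covariance of 0.251. With the controls split 2 and 2, so that no library was shared, the correlation had a median of 0.697 (0.488 to 0.779) and the covariance 0.255 over 6 splits. The 2 of these that also parted the title codes gave 0.584 and 0.488 (covariance 0.226 and 0.20).

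Of the genes changed in each generation 2185 were shared, 1007 higher in both and 1178 lower in both, and 0 moved in opposite directions. Independent lists this large would share 139 genes upward, 182 downward and 319 in opposite directions. Simulated unchanged groups had 0 calls, so 0 to share. With the controls split, the shared count had a median of 837 (738 to 1049). The 6 shared genes with the largest mean fold were Inmt, mt-Nd3, Gzmc, Gzmd, Gzmf and Eno1b, all with values given above, and the shared count fell to 674 when libraries sharing a title code were summed.

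**Figure D4:**
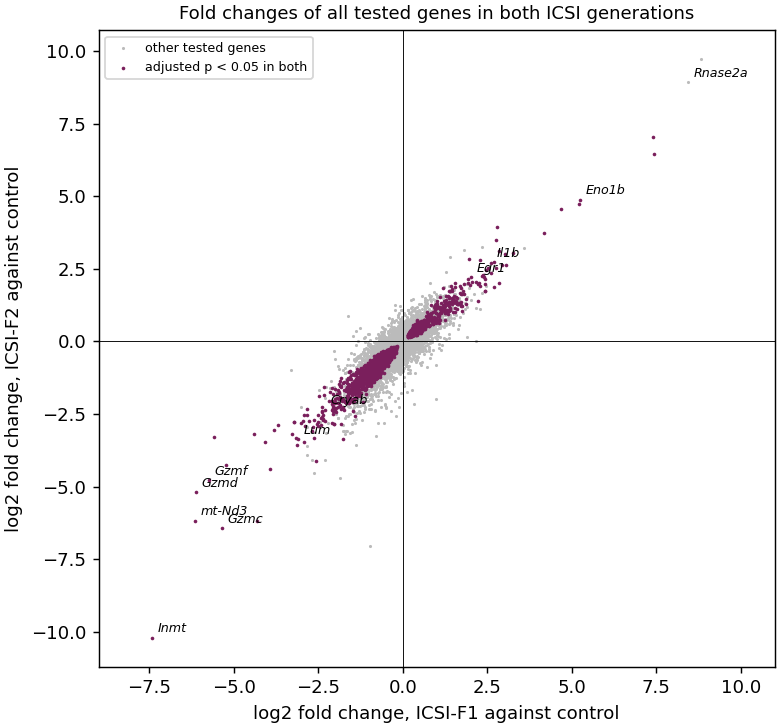
Log2 fold change against control of each of 15521 tested genes in ICSI-F1 (horizontal axis) and ICSI-F2 (vertical axis), with the 2185 genes past an adjusted p of 0.05 in both comparisons in purple and other genes in grey. Pearson's correlation is 0.883, and fitted values of genes near 0 in a group, such as Inmt and Rnase2a, depend on the prior count.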

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

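Chosen only after the results were seen were the Xist test, both tests of score differences and both tests of near-absent genes. The tests of GC and length, of scaling and of other splits were fixed before their results were seen.

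Other splits of the libraries into 4 and 4 were counted for each comparison. For ICSI-F1 against control 1 of 35 splits, the real split with 2988 genes, gave as many genes, and the highest other split gave 0. For ICSI-F2 against control it was again 1 of 35, the real split with 3325 genes, with 0 as the highest other. Chance alone is argued against, at 1 of 35, only if libraries of 1 title code share no other factor, which is not known. For ICSI-F2 against ICSI-F1 the real split gave 0 genes, so 35 of 35 splits gave as many whatever their outcome, which decides nothing, and the highest other gave 5.

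The decidua and the NK and T cell lists had lower medians in both ICSI groups. A GC content or transcript length trend as the whole source is argued against, since offsets for both moved the decidua median by at most 0.0441. Less maternal tissue in the ICSI samples may contribute to the decidua fall, since Xist in libraries with Y-linked reads was 3.23 times as high in controls (315 against 97.7 CPM, with both such controls of 1 title code) and Y-linked CPM 1.20 times as high in ICSI libraries. An even loss of maternal tissue does not account for the lymphocyte fall, since the NK and T cell score fell beyond the decidua score by -2.48 in ICSI-F2 and -2.99 in ICSI-F1 on the log2 scale (exact permutation p = 0.0286 each). An uneven loss, of the layer that holds these cells, a difference between the pregnancies, and any part of less maternal tissue in the fall of maternally expressed imprinted genes stay open and were not tested.

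The spongiotrophoblast and giant cell lists had higher medians in both ICSI groups, past camera at its preset correlation but not at an estimated one (adjusted p = 0.334 and 0.147 in ICSI-F1, 0.570 and 0.113 in ICSI-F2). Scaling moved the spongiotrophoblast median by at most 0.0373 and GC and length offsets moved either median by at most 0.165, so neither accounts for the higher medians as a whole. An even loss of maternal tissue would raise trophoblast lists alike. As sole source it is argued against by the spongiotrophoblast minus syncytiotrophoblast layer II score. This was higher by 1.21 in ICSI-F1 and 0.924 in ICSI-F2 (exact permutation p = 0.0286 each). Such a loss in part, a shift in layers sampled and a difference in placental makeup after ICSI stay open and were not tested.

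Of the genes that changed against control, 38 were near absent on a single side of a comparison that called them, 16 in control and 22 in an ICSI group, where 1 such group sufficed (under 0.25 CPM against at least 1 CPM, limits chosen after seeing the data). Reads shared between near-identical copies stay open as a source, since 5 of 38 such genes (13.2%) against 880 of 15476 others (5.69%) shared at least 20% of 50-mers, an odds ratio of 2.51 (one-sided Fisher's exact p = 0.0631). RNA of another mouse background could give such genes too, but of the 3 of these 38 with at most 3 control reads 0 passed 3 reads in some and not all ICSI libraries. Ifi202b, an interferon-inducible gene over that limit with 7 control reads, did show such a mix, with over 3 reads in 6 of the 8 ICSI libraries, 1 in ICSI-F1 replicate 4 and 0 in ICSI-F2 replicate 3. The count of 0 was first read as excluding another background, but a uniform background also predicts 0, and another background stays open.

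In some groups a single library lay far from the other 3, by a gap to the nearest, as a share of the group's range, above Dixon's 95% critical value. This held for 21 of 386 groups tested (5.44%), where chance gives about 1 in 20, or 19.3. Each share is given with the value and the nearest other value. Adgre1 was highest in ICSI-F2 replicate 3 (0.914, 10.5 CPM against 6.26), and Cnmd was highest in control replicate 3 (0.960, 7.33 CPM against 3.4). Cts6 was lowest in ICSI-F2 replicate 4 (0.930, 1380.1 CPM against 1566), and Ctsk was highest in ICSI-F2 replicate 4 (0.934, 44.1 CPM against 8.48). Cxcl2 was highest in control replicate 1 (0.969, 0.371 CPM against 0.20), and Cxcl2 was highest in ICSI-F2 replicate 3 (0.894, 5.69 CPM against 1.2). Egln3 was highest in ICSI-F1 replicate 4 (0.931, 38 CPM against 19.2), and Gzmb was highest in ICSI-F1 replicate 3 (1.0, 0.0676 CPM against 0). Gzmf was highest in ICSI-F2 replicate 2 (0.936, 1.95 CPM against 0.486), and Ifi202b was lowest in ICSI-F1 replicate 4 (0.874, 0.0559 CPM against 3.79). Igf2bp2 was lowest in ICSI-F2 replicate 1 (0.880, 68.8 CPM against 85.4), and Igfbp3 was lowest in ICSI-F1 replicate 4 (0.834, 66.5 CPM against 107.6). Inmt was highest in ICSI-F1 replicate 4 (1.0, 0.168 CPM against 0), and Lum was highest in ICSI-F1 replicate 1 (0.882, 109 CPM against 45.3). Lyz2 was lowest in ICSI-F1 replicate 1 (0.910, 130.4 CPM against 169), and Nefm was lowest in ICSI-F1 replicate 4 (0.870, 0.670 CPM against 1.76). Prf1 was highest in ICSI-F1 replicate 2 (0.868, 0.349 CPM against 0.143), and Rnase2a was highest in ICSI-F1 replicate 1 (0.921, 49.96 CPM against 4.53). Tmprss11e was highest in ICSI-F2 replicate 2 (0.866, 3.32 CPM against 0.995), and the share of rRNA-like genes was highest in control replicate 3 (0.966, 3.14% against 2.83). The maternal decidua score was lowest in ICSI-F2 replicate 3 (0.886, 5.06 on the log2 scale against 5.27).

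The effects of the generations against control differed for 14 lists by camera with its preset correlation, and for 0 with an estimated correlation or by fry. With adjusted p in parentheses, lower effects in ICSI-F2 were found for imprinted maternally expressed (0.0444), spongiotrophoblast (2.16e-08), fetal endothelium (8.11e-05), stroma and pericyte (0.0171), macrophage (1.56e-04) and erythroid (4.09e-21). The same held for yolk sac endoderm (6.08e-08), cholesterol synthesis (0.0218), angiogenic and vasoactive factors (9.63e-05), interferon response (0.0230), unfolded protein and integrated stress response (7.21e-04) and extracellular matrix and remodelling (2.44e-05). Higher effects were found for uterine NK and T cells (0.00552) and heat shock response (0.00375).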

How the results depend on the processing

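Alternatives added after seeing the data are named under processing. No paired analysis was possible because the replicate numbers follow accession order and the title codes lie within groups. Over all alternatives 11276 values of single genes stayed on their side of the threshold, 431 lost it, 70 gained it and 0 reversed, and for lists the counts were 984, 151, 0 and 4. The 2988 genes of ICSI-F1 fell to 677 and the 3325 of ICSI-F2 to 809 with a 2-fold minimum, by construction. Summing title codes, which leaves fewer samples, gave 797, 1644 and an overlap of 674 against 2185. Limma-voom with a correlation of 0.286 within codes gave 1918 for ICSI-F1. Libraries with Y-linked reads gave 2210 for ICSI-F2, and libraries without gave 1532, 1690 and, between the generations, 146 (66 higher and 80 lower), with fewer samples in each. DESeq2 gave 14 genes between the generations (1 higher and 13 lower) against 0 by edgeR, and the cause was not tested. With an estimated correlation 3, 2 and 0 lists passed against 18, 22 and 14. By fry, a test that does not compare a list with other genes, 18, 20 and 0 passed. Splitting the controls, with fewer samples a fit, gave a correlation of 0.697 against 0.883 and an overlap of 837. Over fits without 1 library, ICSI-F1 gave 1916 (without ICSI-F1 replicate 2) to 3170 genes, ICSI-F2 2417 to 3323 and the generations 0 throughout. The lists past the test ran from 17 to 22, 19 to 25 and 11 to 15, the correlation from 0.824 (without ICSI-F2 replicate 1) to 0.881 and the overlap from 1572 to 2147. In the libraries with Y-linked reads 4 lists reversed without passing, and the cause was not tested. The interferon response in ICSI-F1 had an adjusted p of 0.619 (4.9e-07 to 0.650 over 21 alternatives) and between the generations 0.339 (5.8e-04 to 0.806). In ICSI-F2 the yolk sac endoderm list had 0.505 (7.4e-59 to 0.570) and cholesterol synthesis 0.310 (4.1e-11 to 0.592). Other scalings moved the median of all genes by at most 0.0354. Upper-quartile factors turned the share of higher calls from 46.8% to 56.9% in ICSI-F1, and gave 1976 higher and 1612 lower genes in ICSI-F2. Depth limits folds of genes near 0, which rest on few reads.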

Other observations

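Lists that did not pass their test held genes that changed. Of 25 hypoxia response genes 2 rose and 7 fell, with 2 up and 8 down adjusted over the list alone (camera adjusted p = 0.105). In ICSI-F2 3 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.157). Egln3, an oxygen-sensing prolyl hydroxylase gene, fell from 97.1 ± 29 to 23.2 ± 9.86 and 19.3 ± 3.48 CPM in ICSI-F1 and ICSI-F2. Ankrd37 fell too (log2FC -0.97 ± 0.18 and -1.07 ± 0.18). Of 23 antioxidant and NRF2 genes 4 rose and 4 fell, with 8 up and 5 down adjusted over the list alone (camera adjusted p = 0.236). In ICSI-F2 5 rose and 5 fell, with 7 up and 5 down adjusted over the list alone (camera adjusted p = 0.449). The metallothionein genes Mt1 (-0.73 ± 0.13 and -0.76 ± 0.13 on the log2 scale) and Mt2 (-0.98 ± 0.15 and -0.90 ± 0.15) fell, and the sulfiredoxin gene Srxn1 rose (0.58 ± 0.10 and 0.62 ± 0.10).

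Of 21 genes of the germline list 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.282). In ICSI-F2 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.327). The list holds genes silenced by DNA methylation in most tissues. Rhox5 (log2FC 0.46 ± 0.08, adjusted p = 0.0027 in ICSI-F1 and log2FC 0.50 ± 0.08, adjusted p = 0.0014 in ICSI-F2) and Taf7l (0.74 ± 0.14 and 0.67 ± 0.14) rose. Dppa3 rose in ICSI-F1 (log2FC 3.03 ± 0.85, adjusted p = 0.027) and in ICSI-F2 (log2FC 3.0 ± 0.86, adjusted p = 0.026). In ICSI-F1 that call ended without control replicate 1 (adjusted p = 0.0666), 2 (0.0609), 3 (0.0626), ICSI-F1 replicate 2 (0.0586) or 3 (0.0693), with p-values from 0.0168 to 0.0693 over the 12 fits that each left out 1 library. In ICSI-F2 it ended without control replicate 1 (adjusted p = 0.0665), 2 (0.0594), 3 (0.0604), ICSI-F2 replicate 1 (0.0550) or 3 (0.0815), with p-values from 0.0145 to 0.0815. Of 14 steroid and thyroid hormone genes 2 rose and 2 fell, with 3 up and 2 down adjusted over the list alone (camera adjusted p = 0.508). In ICSI-F2 2 rose and 2 fell, with 2 up and 3 down adjusted over the list alone (camera adjusted p = 0.793). Cyp11a1, which starts steroid synthesis from cholesterol, fell (-0.69 ± 0.15 and -0.91 ± 0.15) and the ferredoxin gene Fdx1 rose (0.48 ± 0.11 and 0.58 ± 0.11). Of 21 insulin-like growth factor axis genes 1 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.331). In ICSI-F2 0 rose and 7 fell, with 1 up and 10 down adjusted over the list alone (camera adjusted p = 0.066). The insulin receptor substrate gene Irs1 (-0.68 ± 0.11 and -0.52 ± 0.10) and Igfbp3 (-0.56 ± 0.16 and -0.85 ± 0.16) fell.

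The measures of spermatid transcripts and of single genes that follow were chosen after their values were seen. Reads of Prm1, Prm2 and Tnp2, genes of late spermatids, numbered 241, 19, 2 and 0 in ICSI-F1 replicates 1 to 4. In ICSI-F2 replicates 1 to 4 they numbered 0, 1, 1 and 40, and each control had 0. Without ICSI-F1 replicate 1 and ICSI-F2 replicate 4, 2640 and 2860 genes changed against control and 0 between the generations. Ang2, a ribonuclease A family gene (mm10 chromosome 14, 51195324 to 51199148), had 0 control reads and 206 and 400 reads in ICSI-F1 and ICSI-F2. It was at least 66.0-fold and 127.9-fold higher, against a floor of 3 counts over the control group, or 9.44-fold without ICSI-F1 replicate 1 and 74.5-fold without ICSI-F2 replicate 4, and each ICSI library had 5 to 226 reads. It did not pass edgeR's test (adjusted p = 0.138 and 0.0857). Gm10503, an antisense gene, had 0 control reads and 84 and 65 reads, at least 26.9-fold and 20.8-fold higher. Gm10260, which shares 54.9% of its 50-mers with other genes, had 1 control read against 267 and 134 reads. The ratios were 257 (95% counting interval 45.7 to 10176) and 129 (22.7 to 5115), or at least 64.0-fold and 32.0-fold without control replicate 3, which held that read.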
